A study of Mus musculus with 6 samples.

How the data were processed

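RNA was measured by sequencing in 6 libraries of mouse primary cardiomyocytes, cells taken directly from heart tissue and kept in culture. Per the labels, 3 libraries came from cells given the control adenovirus (Adv-NC) and 3 from cells given an adenovirus for ABHD11 (Adv-ABHD11), and all cells then spent 24 h in hypoxia. The labels gave the genotype as wild type and the same batch number to every library. They did not say whether the replicates of a group came from separate cultures or animals, so p-values measured only the spread between these samples, which may be technical. Per the labels' protocols, total RNA was extracted with TRIzol and its integrity was assessed on a Bioanalyzer.

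The authors deposited an expected count per gene symbol for each library, estimated and not scaled to library size. Trimmomatic 0.39, HISAT2, RSEM and DESeq2 and the genome build mm10 were named in the submitters' processing notes, without the role of each. The annotation release, the filters on reads and the strandedness of the counting were not given in the sources used here. RSEM shares reads that fit several genes between them by an estimate, so values of near-identical copies, such as the paired alpha-globin and beta-globin genes and Hspa1a with Hspa1b, have an uncertain split. Without known strandedness, reads from overlapping genes on opposite strands cannot be told apart. The mitochondrial pairs mt-Atp8 with mt-Atp6 and mt-Nd4l with mt-Nd4 overlap on the same strand over a short stretch, where the assignment of reads is uncertain. The mitochondrial mRNA counts also depend on how reads matching nuclear copies of mitochondrial DNA were shared.

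Each deposited file held 21763 rows with 21741 distinct symbols, and 5304 rows were at 0 in every library. For the 22 rows that repeated a symbol, which held 0.009% of all counts, the row with the most counts kept the symbol. Expected counts were rounded to whole numbers, since 8.96% to 10.2% of the genes above 0 had a fractional value. Of the symbols, 21073 were found in the GENCODE M21 annotation of GRCm38, the assembly also named mm10, from which coordinates, transcript lengths and GC content were taken. Library totals ran from 16292756 to 20338700 counts, so that 1 count was worth 0.0492 to 0.0614 CPM, the usual unit of counts scaled to a common library size. Floors and intervals of count ratios cover counting error only, whereas the interval of the Abhd11 fold change comes from the edgeR fit and includes the spread between libraries.

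Groups were compared with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), libraries were scaled by TMM, and the quasi-likelihood F test with Benjamini-Hochberg adjustment was applied at an adjusted p under 0.05. Replicate numbers were not used as a block. The standard error of a log2 fold change was its size divided by the square root of F. CPM values were computed on TMM-scaled library sizes and are given as mean ± SD over the 3 libraries of a group. For a gene at 0 in all libraries of a group, the fold was computed against a floor of 3 counts over that group and is a lower bound. With 1 to 3 counts in a group, the ratio of the counts is given with an exact 95% interval from the binomial distribution. The share of counts from mtDNA was compared by a two-sided exact permutation test, which cannot go below 0.1 with 3 libraries against 3.

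Before the data were examined, 31 gene lists were fixed: mitochondrial, metabolic, ferroptosis, stress, inflammatory and contractile genes, and markers of other cell types of a heart preparation. Lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. Listed genes removed by the filter were counted as not tested, and 4 listed genes were not analysed here. The genes to be named were also fixed by rule: Abhd11; per direction the 12 largest changes among genes past the threshold with a mean CPM above 5, no overlap between groups and no provisional symbol; up to 4 members per list with the smallest adjusted p; and the 13 mtDNA-encoded mRNAs with 10 genes of mtDNA transcription, ferroptosis and the TCA cycle. Of the genes that this rule selects, 1 is not reported here. A further 6 lists were written after the gene table had been seen and are named as such.

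The procedure was tested on simulated data for this comparison, with 12797 genes drawn from the real means and library sizes. It recovered 35 of 50 genes changed 1.5-fold, 38 of 50 changed 2-fold, 50 of 50 changed 4-fold and 50 of 50 changed 8-fold, with 7 false calls among 180. Far fewer genes changed in the simulation than were called in the real data, so the adjusted threshold was stricter there. A shifted list was called and 0 of 20 unchanged lists were called by camera. Simulated genes were drawn independently, whereas real list members varied together (estimated correlation 0.885 for cytosolic ribosomal proteins). The simulation therefore does not test the preset correlation on such lists. Alternatives were other scalings, other filters, DESeq2 1.42.0, limma-voom, a replicate block, mtDNA genes and Abhd11 left out of the library sizes, other thresholds and each library left out in turn. The removal of each library's trend on GC content and transcript length was added after seeing the data.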

Results

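The data consisted of RNA-seq counts from 6 libraries of mouse primary cardiomyocytes, 3 labelled Adv-NC and 3 labelled Adv-ABHD11, all after 24 h of hypoxia. Hypoxia is used on cultured heart cells as a model of the loss of oxygen in a heart attack. ABHD11 is a mitochondrial hydrolase of the alpha/beta hydrolase family, and the title of the series links it to mtDNA transcription and to ferroptosis, a form of cell death driven by iron-dependent lipid peroxidation. The only contrast of the design was Adv-ABHD11 against Adv-NC, so it asked how the transcriptome of hypoxic cardiomyocytes differed with the ABHD11 virus. Normoxic cells were not analysed here. The Adv-NC libraries held 18219251, 19544674 and 20338700 counts, and the Adv-ABHD11 libraries 16292756, 18539672 and 19526874.

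The gene carried by the virus was examined first, as a check of the labels. Counts on mouse Abhd11 (ENSMUSG00000040532.14, protein-coding, chromosome 5, 135009152 to 135012175, plus strand, GRCm38) were 584, 675 and 661 in the Adv-NC libraries and 636, 769 and 736 in the Adv-ABHD11 libraries. Its level was 33.5 ± 1.87 CPM with Adv-NC and 38.9 ± 3.25 CPM with Adv-ABHD11 (mean ± SD, n = 3 each), a 1.16-fold difference with a 95% interval of 1.002 to 1.343. The log2 fold change was 0.21 with a standard error of 0.101 (edgeR quasi-likelihood test, adjusted p = 0.0764), which did not pass the threshold, and it passed under 4 of the alternative settings. The annotated gene overlaps Abhd11os and an unverified transcript on the opposite strand, and the strandedness of the counting was not given. The transgene's sequence and species were not given in the sources used here, so counts on the mouse gene need not include its transcripts, and the labels Adv-ABHD11 and Adv-NC were taken as given.

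The transcriptomes of the arms stood far apart. Among 12797 tested genes, 3821 were higher and 3768 lower in the Adv-ABHD11 libraries, 59.3% of the total, and 1035 of the higher and 966 of the lower genes differed at least 2-fold. Log2 CPM correlated at 0.987 to 0.992 within the groups and at 0.926 to 0.937 between them, across genes, and the first principal component held 82.1% of the variance. The values of the groups did not overlap for 63.2% of the genes, against 10% by chance. The median log2 fold change of all genes was 0.017. Upper-quartile scaling shifted it by 0.106 and moved the share of higher genes among the calls from 50.3% to 59.6%, so small changes are relative to the TMM scaling. Of 7 marker lists of other cell types 5 passed camera, and those of leukocytes (median -0.101) and nerve cells (median 0.366) did not. Median log2 fold changes of the lists that passed were 5.52 for red blood cell, 0.811 for smooth muscle, 0.769 for endothelial, -0.273 for fibroblast and -0.594 for epicardial markers.

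The largest increases included transcripts that are typical of other organs and cell types. Scgb1a1, the club cell secretory protein of the airway, had 0 counts in all Adv-NC libraries and 84.7 ± 4.16 CPM with Adv-ABHD11, at least 1660-fold higher, and Sftpc, the surfactant protein C of alveolar type II cells, had 0 counts against 32.2 ± 2.66 CPM, at least 630-fold higher. The beta-globin gene Hbb-bs was 46.0-fold higher at 12.4 ± 0.97 CPM (log2 fold change 5.52, and 6.27 without Adv-NC replicate 1). G0s2, an inhibitor of triglyceride breakdown, rose from 6.68 ± 0.367 to 119.8 ± 9.58 CPM, and Ip6k3, an inositol hexakisphosphate kinase of striated muscle, from 2.18 ± 0.524 to 40.2 ± 2.31 CPM. Skeletal alpha-actin (Acta1) rose 10.2-fold, the smooth muscle protein leiomodin (Lmod1) 9.12-fold and the endothelial transcription factor Sox18 10.5-fold. The others by the same rule were Zbtb8b, a zinc finger protein, at 31.8-fold, the potassium channel subunit Kcne3 at 15.0-fold, the steroid sulfate transporter Slc10a6 at 13.3-fold and the protease inhibitor A2m at 10.2-fold (edgeR, all adjusted p at or below 5.38e-09).

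The largest decreases included serpins, AP-1 genes and inducible HSP70 genes. Serpinb2, the plasminogen activator inhibitor type 2, stood at 16.7 ± 1.47 CPM with Adv-NC and had 0 counts with Adv-ABHD11, at least 298-fold lower, and Has1, a hyaluronan synthase, at 12.9 ± 2.05 CPM and 0 counts, at least 230-fold lower. The AP-1 genes Fosb and Fosl1 were 53.7-fold and 49.3-fold lower, and the nuclear receptor Nr4a3 33.1-fold lower. Hdc, which makes histamine, fell from 49.6 ± 2.95 to 0.852 ± 0.163 CPM. Acod1, which makes itaconate, fell from 14.2 ± 1.33 to 0.303 ± 0.0805 CPM, and Olr1, the receptor for oxidised LDL, from 28.7 ± 4.72 to 0.681 ± 0.149 CPM. The inducible HSP70 genes Hspa1a and Hspa1b, near-identical copies whose counts may be split arbitrarily, fell from 597 ± 78.1 to 14.7 ± 1.10 CPM and from 497 ± 59.0 to 14.9 ± 1.27 CPM. Serpinb9b was 103.4-fold lower (log2 fold change -6.69, and -7.45 without Adv-ABHD11 replicate 3). In edgeR's quasi-likelihood test the adjusted p of each of these decreases was at or below 5.64e-11.

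Transcripts encoded by mtDNA rose in the Adv-ABHD11 libraries, as did nuclear genes of contraction (median log2 fold change 0.936). They took 2.42 ± 0.112% of all counts with Adv-NC and 6.40 ± 1.35% with Adv-ABHD11, 2.64 times as much, with no overlap between the libraries (exact permutation test, two-sided, p = 0.1, the smallest p that 3 against 3 allows). The rise was uneven along the mitochondrial genome. The cytochrome c oxidase subunit mt-Co1 (chromosome M, 5328 to 6872, plus strand) accounted for 2.69 of the 3.98 percentage points, at 0.725 ± 0.0312% against 3.41 ± 0.597% of counts, and without mt-Co1 the share went from 1.70 ± 0.0813% to 2.99 ± 0.804%, 1.76 times as much. Of the 13 mtDNA-encoded mRNAs, 10 were higher, 0 lower and 3 did not pass, and 11 were higher adjusted over the list alone. The median log2 fold change was 0.877 (camera adjusted p = 0.000326, but adjusted p = 0.452 with an estimated correlation). The log2 fold changes were 2.195 ± 0.141 (SE) for mt-Co1, 2.02 ± 0.172 for mt-Nd5 and 2.02 ± 0.246 for mt-Nd6, which lies on the opposite strand and overlaps the end of mt-Nd5. They were 1.33 ± 0.230 for mt-Nd2, 1.06 ± 0.128 for mt-Nd4l, 0.88 ± 0.143 for mt-Nd4, 0.81 ± 0.139 for mt-Nd1, 0.63 ± 0.155 for mt-Atp6 and 0.61 ± 0.150 for mt-Co3. The 3 that did not pass were mt-Co2 at 0.29 ± 0.162 (edgeR adjusted p = 0.131), mt-Cytb at 0.33 ± 0.142 (adjusted p = 0.0578) and mt-Nd3 at -0.08 ± 0.215 (adjusted p = 0.763). The calls of mt-Cytb and mt-Co2 depended on the setting. The mRNA mt-Cytb passed with the replicate block (adjusted p = 0.0195), library size only (0.0318), upper-quartile scaling (0.0155), no filter (0.0243) and without Adv-ABHD11 replicate 1 (0.00499). In turn, mt-Co2 passed with upper-quartile scaling (adjusted p = 0.0446) and without Adv-ABHD11 replicate 1 (0.0135). It was at -0.13 with the GC and length trend removed (0.175).

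Part of the mtDNA values rested on Adv-ABHD11 replicate 2. The log2 fold change of mt-Atp8 was 1.91 ± 0.480, from 7086 counts in that library against 973 and 1253 in the other Adv-ABHD11 libraries, and it was 0.41 without it (DESeq2 adjusted p = 0.0634 with all libraries). Without that library, mt-Nd2 was at 0.84, mt-Atp6 at 0.35, mt-Co3 at 0.36, mt-Co2 at 0.013 and mt-Cytb at 0.12. The value of mt-Nd3 was then -0.58 (edgeR adjusted p = 3.48e-05), and the median of the list was 0.608. With each library's trend on GC content and transcript length removed, an alternative chosen after seeing the data, the median was 0.451, with 10 members higher and 1 lower (mt-Nd3 at -0.77).

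**Figure D1:**
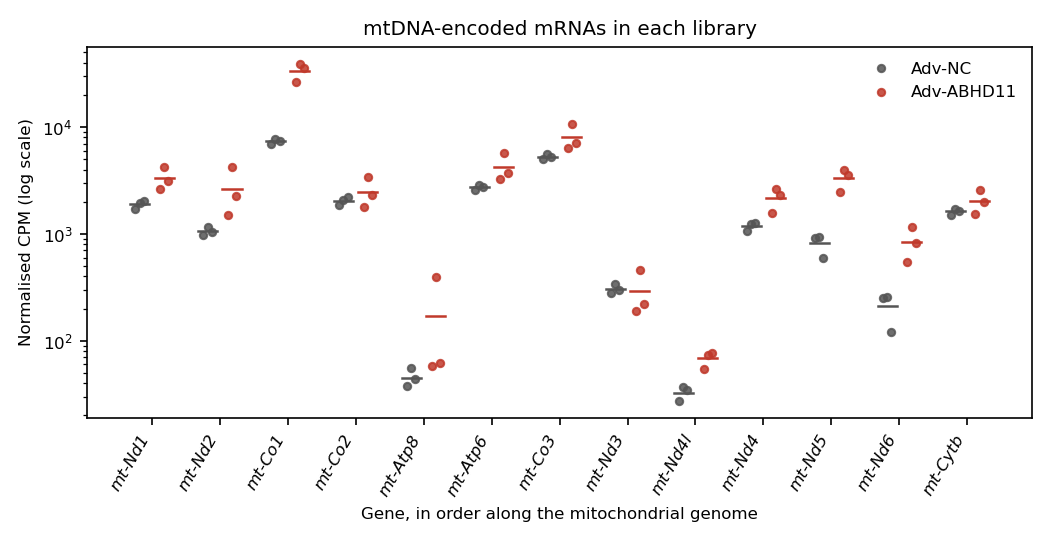
Normalised CPM on a log scale (vertical axis) of the 13 mtDNA-encoded mRNAs, in their order along the mitochondrial genome (horizontal axis), with a point per library and a bar at each group's mean. For mt-Co1 the Adv-ABHD11 mean of 33700 CPM stood above the Adv-NC mean of 7358 CPM, and for mt-Atp8 a single Adv-ABHD11 library stood apart from the other libraries of its group.

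The genes that transcribe and maintain mtDNA did not pass as a list. Of 29 tested members, 4 were higher and 6 lower, or 3 and 6 adjusted over the list alone, and the median log2 fold change was 0.01 (camera adjusted p = 0.872). With upper-quartile scaling the balance turned, to 8 higher and 3 lower. Tfam, the packaging and transcription factor of mtDNA, was at 16.1 ± 1.82 CPM with Adv-NC and 19.1 ± 2.56 CPM with Adv-ABHD11 (edgeR adjusted p = 0.110). The mitochondrial RNA polymerase Polrmt was at 46.9 ± 1.84 and 47.5 ± 6.79 CPM (adjusted p = 0.903), and the transcription factor Tfb2m at 7.37 ± 0.582 and 8.90 ± 1.01 CPM (adjusted p = 0.140). With upper-quartile scaling, Tfam (adjusted p = 0.0304) and Tfb2m (adjusted p = 0.0439) passed, and Polrmt passed at 0.21 after removal of the GC and length trend (adjusted p = 0.0371). The exonuclease Mgme1 rose 2.07-fold and the rRNA methyltransferase Tfb1m 1.86-fold, while the tRNA-processing enzyme Elac2 and the transcription factor Nrf1 fell 1.38-fold and 1.45-fold.

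Nuclear genes of the respiratory chain rose almost without exception, by less than 2-fold each, in the libraries in which contractile genes (median 0.936) and endothelial markers (median 0.769) were also higher. For complex I, 36 of 37 genes were higher and 0 lower, and all 37 were higher adjusted over the list alone, with a median log2 fold change of 0.565 (camera adjusted p = 3.41e-10, but adjusted p = 0.388 with an estimated correlation). Ndufc1 rose from 46.8 ± 4.60 to 90.3 ± 13.5 CPM and Ndufab1 from 292 ± 14.3 to 512 ± 67.1 CPM. For complexes II to V, 42 of 43 were higher and 0 lower, with a median of 0.535 (camera adjusted p = 3.79e-11, but adjusted p = 0.388 with an estimated correlation). Ndufa4 rose from 217 ± 13.96 to 407 ± 47.0 CPM and the striated muscle isoform Cox6a2 from 329 ± 12.5 to 589 ± 35.9 CPM.

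The lists of the TCA cycle and of fatty acid oxidation also passed as higher. In the list of the TCA cycle and lipoylation 21 of 28 were higher and 1 lower (median 0.401, camera adjusted p = 0.000105, adjusted p = 0.117 with an estimated correlation), with fumarase Fh1 at 1.66-fold and the pyruvate dehydrogenase subunit Dlat at 1.63-fold. The kinases that switch off pyruvate dehydrogenase moved in opposite directions, Pdk1 rising 5.11-fold and Pdk4 falling 1.84-fold. Ogdh, the lipoylated 2-oxoglutarate dehydrogenase, was 1.21-fold higher (edgeR adjusted p = 0.0172), a call that was lost without Adv-NC replicate 2 (adjusted p = 0.119) or Adv-ABHD11 replicate 1 (adjusted p = 0.129). In fatty acid oxidation 23 of 30 were higher and 5 lower (median 0.537, camera adjusted p = 0.00099, adjusted p = 0.211 with an estimated correlation). The fatty acid transporter Cd36 rose 2.01-fold and Cpt2 1.67-fold, whereas the lipase inhibitor Angptl4 fell from 77.7 ± 12.1 to 16.2 ± 1.36 CPM and the lipid droplet protein Plin2 1.74-fold. Mitochondrial ribosomal proteins were split, with 16 of 78 higher and 12 lower, or 15 and 11 adjusted over the list alone (median 0.088, camera adjusted p = 0.336). They were 32 higher and 6 lower under upper-quartile scaling, 25 and 11 with library size only, 14 and 18 without Adv-ABHD11 replicate 2, and 19 and 7 without Adv-ABHD11 replicate 3. Genes of mitochondrial proteostasis, dynamics and mitophagy were 12 higher and 5 lower of 28 (median 0.15, camera adjusted p = 0.194), among them the mitophagy receptor Bnip3 at 4.55-fold higher and the autophagy receptor Sqstm1 falling from 4423 ± 362 to 994 ± 37.6 CPM.

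Of the cytosolic ribosomal proteins 37 of 80 were lower and 1 higher, the muscle-specific Rpl3l, with a median log2 fold change of -0.237 (camera adjusted p = 0.000214, but adjusted p = 0.701 with an estimated correlation). Rps19 fell from 466 ± 76.2 to 311 ± 27.7 CPM and Rps18 1.47-fold. The number of lower members was unstable: 18 with upper-quartile scaling, 70 after removal of the GC and length trend, 22 without Adv-NC replicate 2, Adv-NC replicate 3 or Adv-ABHD11 replicate 3, 56 without Adv-NC replicate 1 and 57 without Adv-ABHD11 replicate 2.

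Genes that restrain ferroptosis passed as a lower list, whereas its drivers and markers did not pass, in libraries that also held lung epithelial transcripts (Scgb1a1 at 84.7 CPM). Among suppressors 15 of 29 were lower and 7 higher, with a median log2 fold change of -0.502 (camera adjusted p = 0.0117, but adjusted p = 0.211 with an estimated correlation). Members ran from -4.345 to 1.497. Slc7a11, the cystine transporter that supplies glutathione synthesis, fell from 47.6 ± 15.5 to 2.33 ± 0.378 CPM, a log2 fold change of -4.35 ± 0.223 (SE, edgeR adjusted p = 2.42e-11). Gclm, a subunit of the rate-limiting enzyme of glutathione synthesis, fell 3.91-fold, the thioredoxin reductase Txnrd1 6.41-fold, the quinone reductase Nqo1 7.23-fold and the ferritin heavy chain Fth1 1.79-fold. Gpx4, the peroxidase that removes lipid hydroperoxides, was at 785 ± 87.5 and 751 ± 99.6 CPM, a log2 fold change of -0.06 ± 0.110 (edgeR adjusted p = 0.640) that turned positive with upper-quartile scaling at 0.043, without Adv-NC replicate 2 at 0.0044 and without Adv-ABHD11 replicate 3 at 0.027. Among ferroptosis drivers and markers 10 of 30 were lower and 6 higher, or 10 and 4 adjusted over the list alone (median -0.119, camera adjusted p = 0.109). The lower share was near that of all tested genes, of which 3768 of 12797 were lower. Members of the list ran from -4.575 to 0.784. Its counts were 10 higher and 9 lower with upper-quartile scaling, and the higher members numbered 3 without Adv-NC replicate 2, Adv-ABHD11 replicate 1 or Adv-ABHD11 replicate 3. The prostaglandin synthase Ptgs2, commonly used as a ferroptosis marker, fell from 101 ± 28.4 to 4.25 ± 0.233 CPM (log2 fold change -4.58 ± 0.189, edgeR adjusted p = 1.39e-12). The heme oxygenase Hmox1 fell from 3984 ± 609 to 498 ± 20.01 CPM. The lipid-activating enzyme Acsl4 fell from 37.3 ± 7.94 to 18.2 ± 1.67 CPM, the transferrin receptor Tfrc from 26.0 ± 2.63 to 14.3 ± 1.34 CPM and the polyamine acetyltransferase Sat1 2.66-fold.

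**Figure D2:**
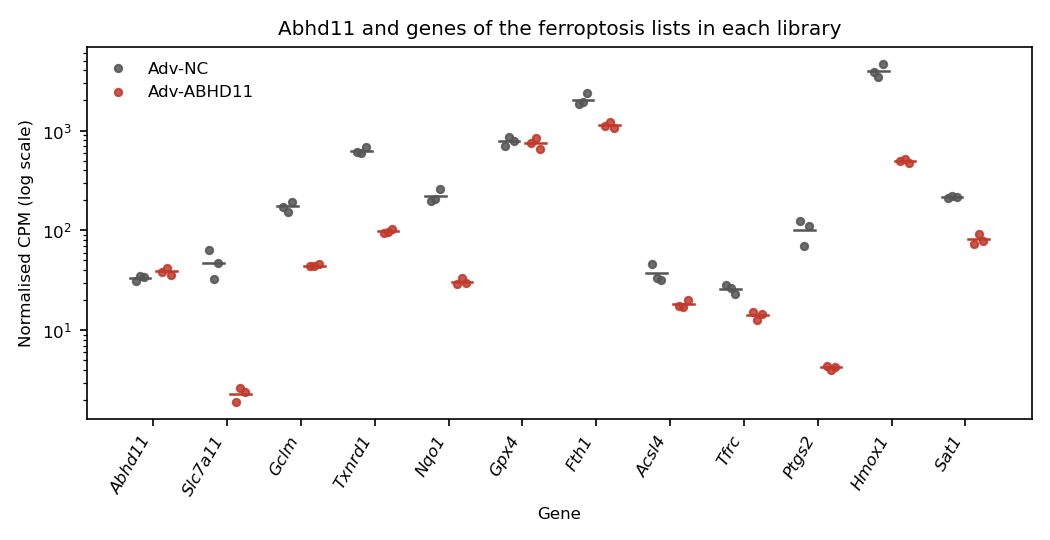
Normalised CPM on a log scale (vertical axis) of Abhd11 and 11 genes of the ferroptosis lists (horizontal axis), with a point per library and a bar at each group's mean. Slc7a11, Ptgs2 and Hmox1 were lower in every Adv-ABHD11 library than in every Adv-NC library, whereas the libraries overlapped for Gpx4 (means 785 and 751 CPM).

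Targets of NRF2, the transcription factor of the antioxidant response, fell as a group: 26 of 31 were lower and 2 higher, or 27 and 2 adjusted over the list alone, with a median log2 fold change of -1.03 (camera adjusted p = 5.2e-12, but adjusted p = 0.211 with an estimated correlation). Some lists share members and are not separate results. Nqo1 and Txnrd1 were also ferroptosis suppressors, and Slc7a11 was in the suppressor and integrated stress response lists. Ptgs2 was in the ferroptosis driver and inflammatory lists, and Atf3 in the ferroptosis driver, integrated stress response and immediate early lists. Srxn1, which repairs peroxiredoxins, fell from 662 ± 66.6 to 38.1 ± 1.58 CPM and Ugdh, which makes UDP-glucuronate, from 309 ± 12.2 to 41.9 ± 2.65 CPM. Hypoxia-responsive and glycolytic genes moved the other way, as did endothelial markers (median 0.769): 34 of 42 were higher and 4 lower, with a median of 0.725 (camera adjusted p = 7.48e-10, but adjusted p = 0.117 with an estimated correlation). The HIF target Egln3, an oxygen-sensing prolyl hydroxylase, rose from 40.9 ± 5.45 to 338 ± 8.48 CPM, Bnip3 from 40.02 ± 3.26 to 182.1 ± 15.6 CPM, Pdk1 from 17.3 ± 1.40 to 88.2 ± 8.03 CPM and the phosphofructokinase Pfkl from 199.6 ± 13.6 to 674 ± 33.9 CPM.

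Immediate early genes, which are switched on within minutes of a stimulus, were lower in the same libraries as fibroblast markers (median -0.273): 26 of 26 passed, with a median log2 fold change of -1.99 (camera adjusted p = 6.06e-17, but adjusted p = 0.134 with an estimated correlation). Atf3 fell from 189 ± 15.1 to 15.1 ± 1.60 CPM and Nr4a1 from 231 ± 19.4 to 9.31 ± 1.11 CPM. Of the inflammatory cytokines and NF-kB targets 20 of 22 were lower and 1 higher, with a median of -1.80 (camera adjusted p = 3.79e-11, but adjusted p = 0.117 with an estimated correlation). The chemokine Ccl5 fell from 91.0 ± 10.3 to 2.92 ± 0.270 CPM and Ccl2 from 126 ± 5.41 to 11.1 ± 0.896 CPM. Interferon response genes were divided, with 16 of 35 higher and 12 lower (median 0.129, camera adjusted p = 0.374): Stat2 rose 3.07-fold while Cxcl10 fell 4.13-fold, Oasl1 3.52-fold and Zbp1 3.03-fold.

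The ER chaperones, the integrated stress response and the cell cycle passed as lower lists. Of the ER chaperones and unfolded protein response genes 15 of 20 were lower and 1 higher (median -0.633, camera adjusted p = 4.3e-05, adjusted p = 0.127 with an estimated correlation), with the stress sensor Ern1 falling 2.70-fold, the chaperone Hyou1 1.95-fold and Hspa5 from 735 ± 50.4 to 405 ± 14.5 CPM. The integrated stress response list held 17 lower and 7 higher of 32 (median -0.29, camera adjusted p = 0.0195, adjusted p = 0.466 with an estimated correlation); the phosphatase subunit Ppp1r15a fell 3.07-fold and the secreted hormone Stc2 rose 3.35-fold. Cell cycle genes were 16 lower and 6 higher of 35 (median -0.207, camera adjusted p = 0.0169, adjusted p = 0.483 with an estimated correlation), and the replication helicase subunit Mcm5 fell from 108.4 ± 7.42 to 34.7 ± 3.00 CPM. Targets of p53 and apoptosis genes went both ways, 10 higher and 11 lower of 30, or 10 and 13 adjusted over the list alone (median -0.014, camera adjusted p = 0.712), and 13 and 10 with upper-quartile scaling, with Ccng1 rising 2.26-fold and Plk2 falling 3.53-fold. Cholesterol and fatty acid synthesis genes were 17 higher and 6 lower of 30 (median 0.307, camera adjusted p = 0.0267, adjusted p = 0.174 with an estimated correlation, and 0.0506 without Adv-ABHD11 replicate 1). The desaturase Scd2 rose from 356 ± 7.81 to 1005 ± 84.3 CPM and Hmgcs1, of the mevalonate pathway, 2.22-fold.

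Cardiomyocyte genes rose together with markers of several other cell types. Of the genes for contraction and calcium handling 36 of 42 were higher and 1 lower, with a median log2 fold change of 0.936 (camera adjusted p = 5.2e-12, but adjusted p = 0.117 with an estimated correlation). The sarcomere protein Fhl2 rose from 417 ± 25.5 to 1021 ± 57.7 CPM and the potassium channel Kcnj2 from 1.53 ± 0.510 to 13.5 ± 3.35 CPM. Fetal and stress genes of cardiomyocytes were 11 higher and 0 lower of 13 (median 0.847, camera adjusted p = 7.57e-06, adjusted p = 0.133 with an estimated correlation), with the slow myosin heavy chain Myh7 rising from 16.8 ± 1.24 to 128.3 ± 16.7 CPM. Endothelial markers were 15 higher and 0 lower of 20 (median 0.769, camera adjusted p = 1.84e-06, adjusted p = 0.197 with an estimated correlation), including the VEGF receptor Kdr at 4.49-fold and the adhesion molecule Pecam1 at 2.51-fold. Smooth muscle and pericyte markers were 11 higher and 1 lower of 15 (median 0.811, camera adjusted p = 0.00041, adjusted p = 0.211 with an estimated correlation), with the myosin kinase Mylk at 4.39-fold and Rgs5 at 3.27-fold. Of 10 red blood cell markers 5 were tested and all 5 were higher, with a median of 5.52, also with Hba-a1 at its bound (camera adjusted p = 0.000371, adjusted p = 0.117 with an estimated correlation). The globins had 0 to 9 counts per Adv-NC library and passed the filter only through the Adv-ABHD11 libraries. Their direction among tested genes is therefore no separate evidence. With no filter, 6 of 7 were higher and 0 lower. Hba-a1 had 0 counts with Adv-NC and was at least 84.8-fold higher, and the near-identical globin copies share reads.

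Markers of fibroblasts and of the epicardium lay lower. Of the fibroblast and extracellular matrix genes 18 of 36 were lower and 6 higher (median -0.273, camera adjusted p = 0.0267, adjusted p = 0.575 with an estimated correlation), a call lost without Adv-NC replicate 1 (adjusted p = 0.0585) or Adv-ABHD11 replicate 2 (adjusted p = 0.077). The protease Mmp3 fell from 382 ± 50.4 to 55.2 ± 4.16 CPM and Timp1 3.08-fold, whereas the fibroblast transcription factor Tcf21 rose 3.08-fold. Epicardial and mesothelial markers were 8 lower and 1 higher of 12 (median -0.594, camera adjusted p = 0.0025, adjusted p = 0.134 with an estimated correlation), with mesothelin (Msln) falling 3.09-fold and the keratin Krt8 3.67-fold. Leukocyte markers did not pass as a list, with 2 of 16 higher and 4 lower, or 2 and 3 adjusted over the list alone (median -0.101, camera adjusted p = 0.722). Csf1r fell 3.00-fold while Lyz2 rose 1.59-fold, and without Adv-NC replicate 3 the counts turned to 4 higher and 2 lower. Among 8 nerve and Schwann cell markers 3 were higher and 3 lower, or 4 and 3 adjusted over the list alone, and the median of 0.366 and the direction of the test differed in sign (camera adjusted p = 0.932). Only 1 was higher with DESeq2 and without Adv-NC replicate 2, Adv-ABHD11 replicate 2 or Adv-ABHD11 replicate 3, and the median was 0.122 without the last and 0.772 with DESeq2. In the ABHD family 3 of 16 tested genes were higher and 6 lower, or 3 and 7 adjusted over the list alone (median -0.067, camera adjusted p = 0.59), with Abhd18 rising 5.90-fold and Abhd2 falling 3.51-fold.

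**Figure D3:**
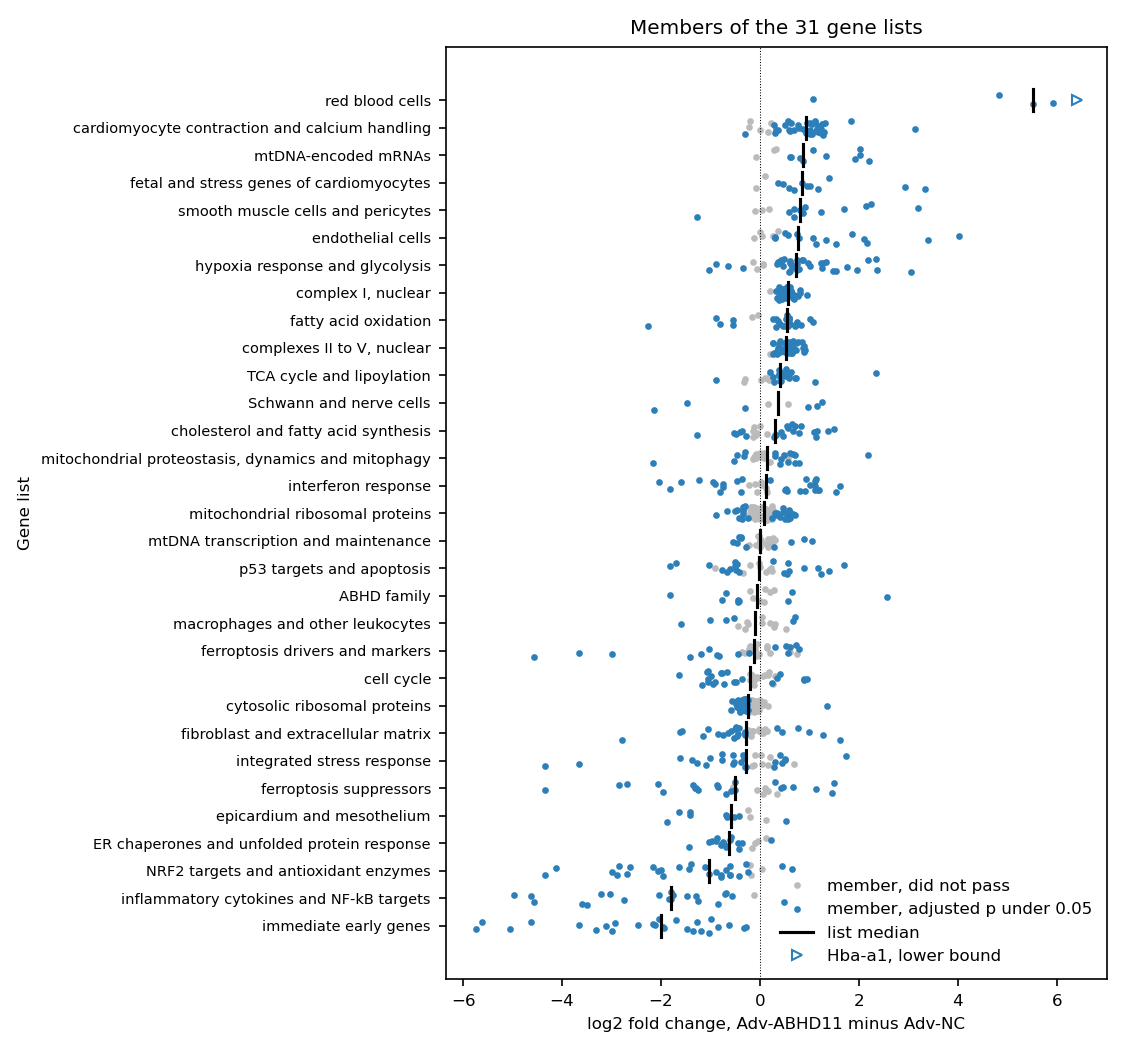
Log2 fold change of Adv-ABHD11 minus Adv-NC (horizontal axis) for each tested member of the 31 gene lists (vertical axis), with blue points for members that passed edgeR's test, grey points for those that did not and a black bar at each list's median. The open triangle is Hba-a1 at its lower bound. Medians ran from -1.99 for immediate early genes to 5.52 for red blood cells.

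A list of lung epithelial genes, written after Scgb1a1, Sftpc and Cbr2 had been seen, was present in the same libraries as all the changes above. Of 22 genes 11 had 0 counts in every Adv-NC library, and of 19 tested 17 were higher and 1 lower. Genes at 0 counts with Adv-NC could pass the filter only through the Adv-ABHD11 libraries. Without those 3 genes, which are no independent evidence, 14 of 16 tested were higher and 1 lower, the median log2 fold change with genes at their bound was 4.82, and the camera adjusted p was 7.23e-08 with the preset and 0.0238 with an estimated correlation. Cyp2f2 was at least 185-fold higher, Sftpa1 at least 112-fold and Scgb3a2 at least 70.5-fold, and Sftpb had 170 counts against 1, a ratio of 182 with a 95% interval of 32.2 to 7220. The whole list summed to 40 CPM (on total counts) with Adv-NC, most of it from Abca3, with 774, 663 and 708 counts there. Without Abca3 the list summed to 2.93 CPM with Adv-NC and 168.8 CPM with Adv-ABHD11.

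**Figure D4:**
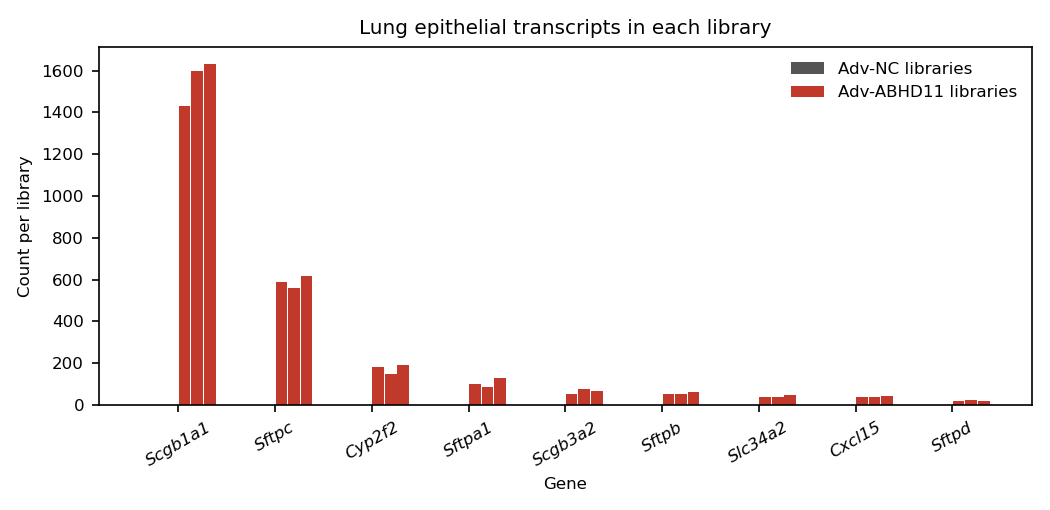
Counts (vertical axis) of 9 lung epithelial genes (horizontal axis) with a bar for each of the 3 Adv-NC and 3 Adv-ABHD11 libraries. Scgb1a1 had 1431, 1599 and 1631 counts in the Adv-ABHD11 libraries, and the Adv-NC libraries had 0 counts of every gene shown except 1 count of Sftpb.

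No list passed with an estimated correlation among the 31 fixed before the data were examined, while 22 passed with the preset correlation. Of those called, the TCA cycle (estimated correlation 0.0029), cholesterol synthesis (-0.00886) and red blood cell (-0.107) lists lay below the preset 0.01, the others above. The lists below it also lost their call (camera adjusted p = 0.117, 0.174 and 0.117), so correlation between members does not account for their loss. Why the test with an estimated correlation was stricter for them was not tested. For 21 lists the counts adjusted over the list alone equalled those over all genes tested, and the other lists have both counts above.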

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

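Of the alternative settings, the removal of the GC and length trend was chosen after the results were seen. The total of calls ran from 6586 to 8114 over 16 alternative fits, against 7589, and every call shared with the reported one had the same direction. At a 2-fold minimum the counts were 1035 higher and 966 lower, since that threshold removes smaller changes. Abhd11 passed with library size only (0.2543), upper-quartile scaling (0.3198), the GC and length trend removed (0.3263) and the replicate block (0.2122, just under the threshold), and over the left-out libraries it ran from 0.155 to 0.259; the cause was not tested. The replicate block moved the calls to 3933 higher and 3907 lower. Same-numbered libraries deviated together at 0.0106, 0.205 and -0.104, across genes, and not every library correlated best with its own number, so the numbers were not taken as pairs.

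Of 151 other named genes 141 kept their call and direction under every alternative run and 4 changed direction, for a cause not tested. Gpx4 reached 0.0428 with upper-quartile scaling and ran from -0.1493 to 0.0269 over the left-out libraries, mt-Nd3 reached 0.0224 and ran from -0.5793 to 0.1339, Polrmt ran from -0.1128 to 0.1168, and mt-Co2 was at -0.1262 with the GC and length trend removed. The mtDNA share difference ran from 3.34 to 4.69 points. Of the 22 lists called, 20 kept their call under every scaling, filter and left-out library, and 0 of the 31 passed with an estimated correlation (adjusted p from 0.117 to 0.933), which was 0.452 for mtDNA-encoded mRNAs and 0.211 for ferroptosis suppressors. In fry, which does not compare a list with other genes, the cytosolic ribosomal proteins were lost (0.166) and 6 lists were gained, among them the ferroptosis drivers and markers (5.07e-05). Lists that had not passed changed direction: leukocytes (adjusted p = 0.832 with no filter, 0.567 to 0.95 over the left-out libraries), nerve cells (0.832 with no filter, 0.974 with the CPM filter) and mtDNA transcription (0.73 to 0.994 over the left-out libraries). For the DESeq2 and limma-voom settings no separate camera test was run. With 3 libraries per group, the simulated data gave 35 of 50 recovered calls at 1.5-fold. The simulation held 180 calls against 7589 in the real comparison, which made its adjusted threshold stricter. That recovery therefore does not carry over to the real comparison, in which small changes can still be missed.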

Other observations

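The gene lists in this part, and the tests named one library, share of cardiomyocytes, handling, depth, transgene and removal of the GC and length trend, were chosen only after the results were seen. Genes of the Notch pathway were mostly higher in the Adv-ABHD11 libraries: 11 of 13 were higher and 2 lower, with a median log2 fold change of 1.24 (camera adjusted p = 0.000546, adjusted p = 0.231 with an estimated correlation). Without Notch3, which the smooth muscle list also holds, the camera adjusted p was 0.00182. The ligand Dll4 rose from 4.24 ± 1.04 to 26.5 ± 1.10 CPM (mean ± SD, n = 3 libraries each) and the target genes Heyl and Hey1 rose 4.82-fold and 7.78-fold, while the receptor Notch2 fell from 76.5 ± 15.99 to 26.3 ± 5.54 CPM. Several of these genes are expressed in blood vessel cells, whose markers were also higher (endothelial median 0.769). Among clock genes 6 of 16 were higher and 3 lower (camera adjusted p = 0.334), with Dbp rising 3.12-fold. Glucocorticoid-induced genes were 4 higher and 9 lower of 17 (camera adjusted p = 0.11), with Klf15 rising 6.16-fold and Sgk1 falling from 136.8 ± 15.0 to 38.3 ± 1.06 CPM.

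Of the proteasome subunits 32 of 37 were lower and 0 higher (median -0.423, camera adjusted p = 7.2e-08, adjusted p = 0.357 with an estimated correlation), with Psmd8 falling from 475 ± 51.0 to 227 ± 20.1 CPM. Of the heat shock chaperones 11 of 24 were lower and 4 higher (median -0.163, camera adjusted p = 0.0221, adjusted p = 0.231 with an estimated correlation). That list was written after Hspa1a and Hspa1b had been seen, and without both 9 of 22 were lower and 4 higher and it did not pass (median -0.093, camera adjusted p = 0.148). The co-chaperones Dnajb1 and Bag3 fell from 172.9 ± 8.83 to 56.8 ± 5.54 CPM and from 316 ± 34.4 to 172.3 ± 16.9 CPM, while the muscle chaperone Cryab rose from 1037 ± 80.7 to 1494 ± 80.4 CPM. Fibroblast markers were lower in the same libraries (median -0.273).

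Lung epithelial transcripts were present in the Adv-ABHD11 libraries and nearly absent from the Adv-NC libraries. They did not come from 1 library, since the lowest count of Scgb1a1 or Sftpc in an Adv-ABHD11 library was 561. A candidate source is RNA of lung epithelial cells in the Adv-ABHD11 samples: of 19 further lung markers 14 were higher, and the abundant Sftpa1, Sftpb, Scgb3a2 and Cyp2f2 had at least 53 counts in each Adv-ABHD11 library, although 11 of the 22 listed genes also had counts with Adv-NC. Whether each arm had its own cell preparation stays open, since 1 of 4 Y-linked genes passed (Kdm5d, log2 fold change 0.66, edgeR adjusted p = 0.0165), which equal pools of animals could also give. At which step such RNA entered, and whether the arms then differed in more than the virus, was not tested.

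Most tested genes differed between the arms, 7589 at the adjusted threshold. A larger share of cardiomyocytes alone in the Adv-ABHD11 cultures, with the other cell types in fixed proportion, would lower the markers of those types alike. The endothelial median lay 1.042 above the fibroblast median on the log2 scale (permutation of genes between the 2 lists, p = 3e-05). That p treats genes as independent, although members varied together (estimated correlation 0.211 and 0.27), and does not measure the spread between libraries. Over the alternative settings the endothelial median ran from 0.714 to 0.876 and the fibroblast median from -0.351 to -0.167. The difference in medians argues against this case only. A mix in which several cell types changed stays open, since the test does not cover it. Median log2 fold changes were 0.936 for contraction, 0.811 for smooth muscle, 0.769 for endothelial, -0.273 for fibroblast and -0.594 for epicardial genes. A GC or length bias as the source of most calls is argued against by 91.5% of them being kept in direction after each library's trend was removed, with values for 98.2% of the tested genes. Single lists moved more. The mtDNA median went from 0.877 to 0.451, and the lower cytosolic ribosomal proteins from 37 to 70, so a share of those changes may follow the trend. Separate preparation or handling of the arms stays open: it may change immediate early genes, of which 26 were lower, but it cannot be told apart from the virus because the labels record no preparation within an arm, and an effect of ABHD11 itself stays open as well. The 10 possible splits of the 6 libraries are too few for a share under 0.05. The real split alone, 1 of 10, gave 7589 genes, and the highest other gave 0 by edgeR (409 at an unadjusted p under 0.05). Every other split mixed libraries of both arms in each group, so the difference between the arms raised the spread within groups. No conclusion on chance is drawn from these counts.

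Abhd11 counts differed little between the arms for a gene named as overexpressed. Depth is argued against, because the upper limit of the fold change was 1.343. An exchange of single libraries between the arms is argued against too, since 6 of 6 libraries correlated better with both libraries of their own arm than with any of the other, which says nothing of an exchange of whole arms. A transgene whose sequence was not counted as mouse Abhd11, for example a version from another species or with changed codons, could leave the fold at 1.16 and stays open, since its sequence is not given in the sources used here; whether the virus raised ABHD11 at all stays open too.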
